A study of Homo sapiens with 12 samples.

How the data were processed

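Polyadenylated RNA of SUM159 cells, an established triple-negative breast cancer line, was sequenced in 12 libraries that fall into 4 groups of 3. The groups combine a control hairpin (shCTRL) or a hairpin against E4F1 (shE4F1) with no treatment or 140 nM gemcitabine for 24 h, per the labels. Libraries were made with a stranded mRNA kit and read as single-end reads of 50 bases, per the labels. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

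The authors' upstream tools were bcl2fastq, FastQC, Bowtie2 2.2.9, TopHat2 2.1.1, HTSeq 0.9.0, DESeq2 1.14.1 and R 3.4.0, with the genome build GRCh38.p7, per the submitters' processing notes. The annotation release, the strand setting of the counting, filters and the design formula are not given in the sources used here. Reads shared between near-identical copies, such as histone genes, SLC2A14 and its paralog, and mitochondrial pseudogenes, can therefore be split in ways that are unknown here.

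All values rest on 4 comparison tables deposited by the authors. Each table gives, per the file headers, a mean of normalized counts over the libraries compared, a log2 fold change with its standard error (SE), a Wald score (the log2 fold change divided by its SE), and a p-value with its Benjamini-Hochberg adjusted p-value, all from the authors' DESeq2. Fold changes of low genes were moderated towards 0 as far as the deposited values show: genes with a mean normalized count under 10 reached at most 2.57 in the untreated knockdown table. Missing adjusted p-values were left missing. A count table of the series has 12 columns whose names match no label, so none of its 12 columns was used, and no level, depth, spread or separation of groups per library was computed. Precision is instead given by the SE and the mean normalized count: in the untreated knockdown table the median SE was 0.242, against 0.530 for genes with a mean under 10 and 0.149 for genes with a mean of 1000 or more.

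The 4 tables compare shE4F1 with shCTRL untreated, shE4F1 with shCTRL under gemcitabine, gemcitabine with untreated in shCTRL cells, and shE4F1 under gemcitabine with shCTRL untreated. A further 2 comparisons were derived from them with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 in Python 3.11.15. The gemcitabine effect in shE4F1 cells is the last table minus the first, and its SE, from the summed variances, counts the shared shCTRL untreated libraries in both and is therefore too large. The interaction is the knockdown effect under gemcitabine minus that in untreated cells, which share no library. Both were tested with a two-sided normal test and adjusted by Benjamini-Hochberg over 21080 and 20923 genes. The table of the knockdown under gemcitabine and that of gemcitabine in shCTRL cells add up to the last table within 0.1 (log2) for 93.4% of 20913 genes, and for 99.4% of the 6755 with a mean of 1000 or more. Differences for the interaction were simulated over 20923 genes with 200 changed, with normal noise of the deposited SEs, as the test assumes. Of differences of 1 (log2) 48.5% were found, 96.0% of those in genes with a mean of 1000 or more, and 3.00% of calls were false. For differences of 2, 71.0% were found and 5.33% of calls were false. Moderation of fold changes and wrongly estimated SEs were not simulated, so these shares cannot show their effect.

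A gene was called changed at an adjusted p under 0.05. The 23 gene lists were fixed before the data were examined: E4F1 targets, PIKK kinases and the TTT-R2TP complex, DNA damage checkpoint, homologous recombination and Fanconi, end joining, p53 targets, DNA replication, G2/M, replication-dependent histones, gemcitabine metabolism, interferon response, NF-kB and cytokines, pyruvate oxidation and TCA cycle, nuclear-encoded respiratory chain, mitochondrially encoded mRNAs, glycolysis, apoptosis regulators, integrated stress response, cholesterol synthesis, mesenchymal and stem-like markers, luminal epithelial markers, blood cell markers and endothelial markers. Each list was set against all other genes with limma 3.58.1 in R 4.3.3 (cameraPR, Wald score, preset inter-gene correlation of 0.01), adjusted over the 23 lists of a comparison. The test scales by the spread of the scores over all genes, which differs between comparisons. The p-values of a list are therefore not comparable across comparisons. No per-library values were used, so an estimated correlation could not be computed and no call is known to hold with one. In a simulation, independent standard normal scores were drawn for the genes of the untreated knockdown table (21563 genes, 200 draws). The DNA replication list, the only one shifted (by 1.5 units of the score), was found in 100% of draws. Of the other lists 0.136% were called. Such draws cannot show how the test behaves for correlated genes, for wider scores or for smaller shifted lists. Another 20 gene families were chosen after the data were seen and tested with cameraPR as the lists were.

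The planned count tests of the design could not be run without mapped columns. The authors' tests took their place, and this was decided once the columns were seen. Named genes followed a rule fixed before the data were examined, with changes that this forced. E4F1, TTI2, CHEK1, ATM, ATR and CDKN1A are always named. Per comparison the 6 largest called rises and falls with a mean normalized count of at least 50 are named, in place of a minimum in CPM and of a separation of the libraries; clone-based names were passed over. Per list up to 4 members with the smallest adjusted p are named, of which a part is given; a few genes that the rule names are not reported here. The fourth table, which was not in that rule, was treated the same way. Of 23375 gene identifiers, 23226 (99.4%) were found in GENCODE 29 on GRCh38, which gave coordinates and 3′ UTR sequences.

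Words of 7 bases were counted in the longest annotated 3′ UTR (at least 50 bases) of 11372 genes with a mean of at least 50, and compared between gene sets in 50 strata of UTR length and GC content (Mantel-Haenszel, Bonferroni over all words). Alternatives were an added minimum fold change, a stricter adjusted p, adjustment over other gene sets, centring of the fold changes, other tables for the same difference, a smaller variance for the derived comparison, and other statistics for the lists and for correlations. Figures were drawn with matplotlib 3.10.9.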

Results

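The data cover the transcriptome of SUM159 cells, a triple-negative breast cancer line, with and without a hairpin against E4F1, a zinc finger transcription factor, and with and without gemcitabine. Gemcitabine is a deoxycytidine analogue that blocks DNA synthesis; it was given at 140 nM for 24 h. Each of the 4 groups held 3 libraries. Values are log2 fold changes ± SE from the authors' deposited tables, or differences between these tables where stated, and "rose" and "fell" mean an adjusted p under 0.05. Depth per library is unknown here; the median SE was 0.242 in the untreated knockdown table, 0.206 in the gemcitabine knockdown table, 0.239 for gemcitabine in shCTRL cells and 0.249 in the table of both changes.

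E4F1 itself (ENSG00000167967, chromosome 16, 2223566 to 2235742, plus strand, GRCh38) was lower with shE4F1 in both conditions. In untreated cells it stood at 0.503 times the shCTRL level in the authors' deposited table, a log2 change of -0.99 (SE 0.26, adjusted p = 0.000778). Under gemcitabine the authors' deposited table gives 0.532 times the shCTRL level, a log2 change of -0.91 (SE 0.16, adjusted p = 1.47e-07). Taken from the other 2 tables of the same triangle the change was -0.89 with adjusted p = 0.0772. The difference between these knockdown effects was 0.08 (SE 0.31, adjusted p = 0.951). Gemcitabine alone gave -0.29 (SE 0.25, adjusted p = 0.433) in shCTRL cells in the authors' deposited table.

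The first comparison asks which genes differ between shE4F1 and shCTRL cells without drug. As lists, DNA replication, homologous recombination, G2/M and the integrated stress response were called down, and histone, interferon-response and mesenchymal genes up. Of 19472 genes with an adjusted p, 7149 changed, 3398 up and 3751 down; 2637 of these changed by at least 1 (log2), 1363 up and 1274 down. The largest falls in the authors' deposited table were INHBE, an activin subunit, at -3.82 ± 0.30, FBXO39 at -3.48 ± 0.32, the imprinted gene MEST at -3.43 ± 0.20, MAD2L2, a translesion synthesis and end-protection factor, at -3.36 ± 0.21, CKS1B, a subunit of cyclin-dependent kinases, at -3.35 ± 0.16, and the small GTPase gene RAB32 at -3.27 ± 0.17. Among the largest rises in the authors' deposited table were HMGA2, an architectural chromatin protein, at 4.38 ± 0.22, RANBP3L at 4.02 ± 0.34, MRO at 3.54 ± 0.30, the ubiquitin ligase gene RNF152 at 3.42 ± 0.20 and the kinesin gene KIF26B at 3.33 ± 0.39.

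DNA replication genes fell together in untreated shE4F1 cells: 33 of 38 fell and none rose (35 fell adjusted over the list alone), with a median of -1.09 and a list test at adjusted p = 6.92e-20. ORC6 of the origin recognition complex fell by 2.03 ± 0.17, GINS4 by 2.58 ± 0.23, the helicase loader CDC6 by 1.63 ± 0.17 and the clamp loader subunit RFC2 by 1.30 ± 0.14 in the authors' deposited table. Homologous recombination and Fanconi genes fell in 24 of 29 cases, also adjusted over the list alone, with none rising (median -1.03, adjusted p = 6.32e-16). XRCC3 fell by 1.62 ± 0.19, FANCE by 1.57 ± 0.17 and BRCA1 by 1.40 ± 0.16 in the authors' deposited table. Of 32 G2/M genes 22 fell (27 adjusted over the list alone) and none rose (median -0.62, adjusted p = 2.02e-07), among them the survivin gene BIRC5 at -1.2 ± 0.16 and the centromeric histone gene CENPA at -1.23 ± 0.18 in the authors' deposited table. In the DNA damage checkpoint list 10 of 22 fell and 2 rose, the same counts adjusted over the list alone (median -0.36, adjusted p = 0.0187). TIMELESS was at -1.89 ± 0.20 and the phosphatase gene CDC25A at 0.71 ± 0.15 in the authors' deposited table. The call of the checkpoint list was lost among genes with a mean of 50 or more (adjusted p = 0.124) and with the log2 change as the statistic (adjusted p = 0.0554).

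The integrated stress response list holds targets of the transcription factors ATF4 and CHOP, amino acid synthesis and transport genes among them, and unfolded protein response genes. It fell in 17 of 20 cases in untreated shE4F1 cells, also adjusted over the list alone (median -1.47, list test adjusted p = 3.11e-16). The pseudokinase gene TRIB3 fell by 3.14 ± 0.25, the folate enzyme gene MTHFD2 by 2.56 ± 0.17, the asparagine synthetase gene ASNS by 2.49 ± 0.21 and the amino acid transporter gene SLC7A5 by 2.36 ± 0.20 in the authors' deposited table. Replication-dependent histone genes rose in 13 of 40 cases and fell in 1, as adjusted over the list alone (median 0.44, adjusted p = 0.00122), led by HIST1H4H at 2.70 ± 0.23 and HIST1H2AC at 2.1 ± 0.18 in the authors' deposited table. Only 13 of these 40 histone genes had a mean of 50 or more, among which the list stayed called (adjusted p = 1.96e-05). Most histone mRNA lacks a poly(A) tail and the libraries hold polyadenylated RNA, so these values need not follow total histone mRNA. Of 32 interferon-response genes 14 rose and 3 fell (17 and 4 adjusted over the list alone; median 0.64, adjusted p = 0.00023). The chemokine gene CCL5 was at 2.37 ± 0.27 and IFI44L at 1.92 ± 0.22 in the authors' deposited table. Mesenchymal and stem-like markers rose in 11 of 19 cases and fell in 4 (12 and 4 adjusted over the list alone; median 0.79, adjusted p = 0.0108). Fibronectin, FN1, rose by 2.1 ± 0.19 and the collagen gene COL1A1 fell by 1.51 ± 0.21 in the authors' deposited table. Mitochondrially encoded mRNAs rose in 5 of 13 cases, also adjusted over the list alone (median 0.32, adjusted p = 0.0182, and 0.211 with the log2 change as the statistic), and MT-ND1 rose by 0.50 ± 0.13 in the authors' deposited table.

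The list of 8 E4F1 targets was recalled from memory of earlier work, and binding of E4F1 in these cells was not examined. In untreated cells 3 of the 8 fell and none rose (4 fell adjusted over the list alone), with a median of -0.34 and no call for the list (adjusted p = 0.13). DLAT, of the pyruvate dehydrogenase complex, fell by 0.50 ± 0.15 in the authors' deposited table. TTI2, a cofactor that stabilises the PIKK kinases, fell by 0.36 ± 0.15 (adjusted p = 0.0496), a call that centring on the median ended (adjusted p = 0.0987), while the checkpoint kinase gene CHEK1 stood at -0.32 ± 0.16 (adjusted p = 0.108), both in the authors' deposited table. The PIKK and TTT-R2TP list had 6 of 13 members lower and 2 higher (7 and 3 adjusted over the list alone) and no call (median -0.33, adjusted p = 0.52). ATM rose by 0.55 ± 0.14, MTOR rose by 0.54 ± 0.13, RUVBL2 fell by 0.76 ± 0.15 and ATR was at 0.25 ± 0.14 (adjusted p = 0.171) in the authors' deposited table. Of 29 p53 targets 10 fell and 4 rose, as adjusted over the list alone, with no call (median -0.18, adjusted p = 0.468). BTG2 rose by 2.30 ± 0.20, DDB2 fell by 1.69 ± 0.21 and CDKN1A was at -0.21 ± 0.17 (adjusted p = 0.364) in the authors' deposited table.

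Among the other lists in untreated cells, gemcitabine metabolism had 8 of 17 members lower and 3 higher, as adjusted over the list alone (median -0.36, adjusted p = 0.263). The deaminase gene DCTD fell by 1.45 ± 0.14, the efflux pump gene ABCC5 rose by 1.55 ± 0.15 and the dNTPase gene SAMHD1 rose by 1.31 ± 0.17 in the authors' deposited table. NF-kB and cytokine genes went both ways, 11 of 23 lower and 4 higher, as adjusted over the list alone (median -0.30, adjusted p = 0.263). MMP3 was at 3.19 ± 0.19 and CCL20 at -2.94 ± 0.23 in the authors' deposited table. Apoptosis regulators had 6 of 20 higher and 8 lower, as adjusted over the list alone. Their median was -0.10 while the list test pointed up (adjusted p = 0.948). BMF was at 2.62 ± 0.25 and CASP9 at -1.93 ± 0.20 in the authors' deposited table. End joining (4 of 11 lower, also adjusted over the list alone; median -0.31) was not called at adjusted p = 0.0634, and was called with ranks as the statistic (adjusted p = 0.0213). No call was made for pyruvate oxidation and the TCA cycle (10 of 30 lower and 4 higher, adjusted p = 0.174), the nuclear-encoded respiratory chain (5 of 41 lower and 4 higher, adjusted p = 0.525), glycolysis (4 of 20 lower and 2 higher, adjusted p = 0.468) or cholesterol synthesis (2 of 18 higher, adjusted p = 0.468). Adjusted over the list alone these counts were 10 and 4, 4 and 4, 4 and 2, and 0. Of markers of other cell types, luminal epithelial markers had 2 of 10 lower and 1 higher, as adjusted over the list alone (adjusted p = 0.525, median 0.02 but a test pointing down). Blood cell markers had 2 of 5 lower, also adjusted over the list alone (adjusted p = 0.151, and 0.0160 with the log2 change as the statistic). Endothelial markers rose in 3 of 6 cases (4 adjusted over the list alone; median 1.01, adjusted p = 0.00944, and 0.0631 with ranks). The receptor gene KDR was at 2.34 ± 0.20 in the authors' deposited table.

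The 3′ UTRs of MEST, MAD2L2, RAB32, GINS4, CDC6, MTHFD2, SLC7A5, DCTD, CASP9, ATM, CDKN1A, MRO and RNF152 contain the 7-base word AAGTGCT. Of 666 genes lower by at least 1 (log2) in both knockdown tables, 471 had a mean of at least 50 and a searched 3′ UTR. The word lay in 39.7% of these 471 and in 22.9% of other searched genes.

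The second comparison asks the same under gemcitabine. As lists, replication and recombination genes were again called down and histone and mitochondrial mRNAs up, and cytokine genes were called down. Of 22433 genes 9202 changed, 4546 up and 4656 down, and 3048 changed by at least 1 (log2), 1416 up and 1632 down. The largest falls in the authors' deposited table were ACTBL2, a beta-actin-like gene, at -4.41 ± 0.28, the tyrosine phosphatase gene PTPRR at -3.72 ± 0.17, TRIML2 at -3.69 ± 0.27, the carboxypeptidase gene CPA3 at -3.68 ± 0.32, IL1B at -3.65 ± 0.24 and the synaptotagmin gene SYT1 at -3.34 ± 0.15. The largest rises in the authors' deposited table were HIST1H2AC at 4.74 ± 0.18, MRO at 3.92 ± 0.28, KRTAP7-1 at 3.86 ± 0.28, the glucose transporter gene SLC2A14 at 3.62 ± 0.29, HMGA2 at 3.35 ± 0.33 and IFITM10 at 3.25 ± 0.34.

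Under gemcitabine 37 of 38 DNA replication genes were lower in shE4F1 cells (38 adjusted over the list alone; median -0.79, adjusted p = 2.81e-19). GINS4 was at -2.88 ± 0.15, CDC6 at -1.71 ± 0.12 and the helicase subunit gene MCM7 at -1.37 ± 0.12 in the authors' deposited table. Homologous recombination and Fanconi genes fell in 21 of 29 cases and rose in 1 (23 and 1 adjusted over the list alone; median -0.55, adjusted p = 4.03e-06). Of 25 NF-kB and cytokine genes 19 fell and 3 rose, as adjusted over the list alone (median -1.30, adjusted p = 2.30e-08). IL6 fell by 2.69 ± 0.15, IL1A fell by 2.78 ± 0.16 and MMP3 rose by 2.72 ± 0.16 in the authors' deposited table. Histone genes rose in 23 of 35 cases and fell in 1, as adjusted over the list alone (median 1.13, adjusted p = 1.27e-08). Only 11 of these 35 had a mean of 50 or more, and the limit of polyadenylated RNA holds here too. HIST1H2BD was at 3.24 ± 0.22 in the authors' deposited table. Mitochondrially encoded mRNAs rose in 12 of 13 cases, also adjusted over the list alone (median 0.71, adjusted p = 4.03e-06). MT-CYB was at 0.93 ± 0.12 in the authors' deposited table. These shCTRL gemcitabine libraries also enter the table of the drug effect in shCTRL cells, in which the cytokine list was called up and the histone and mitochondrial lists down.

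G2/M genes fell in 20 of 32 cases and rose in 2 under gemcitabine (21 and 2 adjusted over the list alone; median -0.40, adjusted p = 0.00312, and 0.0510 with the log2 change as the statistic). KIF2C fell by 1.05 ± 0.13 and the kinesin gene KIF20A rose by 1.02 ± 0.17 in the authors' deposited table. The integrated stress response list had 10 of 20 lower and 4 higher (10 and 6 adjusted over the list alone; median -0.24, adjusted p = 0.00495), a call lost with ranks (adjusted p = 0.262) and with the log2 change (adjusted p = 0.127). The stress transcription factor gene ATF3 was at -3.24 ± 0.17 in the authors' deposited table. For p53 targets 12 of 29 fell and 10 rose, as adjusted over the list alone, without a call (median -0.10, adjusted p = 0.142). The cell cycle inhibitor gene CDKN1A fell by 1.13 ± 0.13, GADD45A by 2.11 ± 0.10 and GDF15 by 2.46 ± 0.16, while TP53INP1 rose by 2.21 ± 0.20, in the authors' deposited table. E4F1 targets were split, with 3 of 8 lower and 2 higher, as adjusted over the list alone (median -0.13, adjusted p = 0.544). TTI2 fell by 0.35 ± 0.14 and CHEK1 by 0.29 ± 0.11, and ELP3, of the Elongator complex, rose by 0.38 ± 0.10, in the authors' deposited table. Taken from the other 2 tables, whose difference has a larger SE, the calls of TTI2, CHEK1, ELP3 and KIF20A were lost (adjusted p = 0.325, 0.494, 0.332 and 0.0812). Endothelial markers were called up (3 of 7 higher, also adjusted over the list alone; median 0.05, adjusted p = 0.0177) and blood cell markers down (2 of 5 lower and 1 higher, as adjusted over the list alone; median -0.67, adjusted p = 0.0366), and neither call held with ranks (adjusted p = 0.262 and 0.235). KDR rose by 2.92 ± 0.14 and the leukocyte gene PTPRC fell by 3.00 ± 0.27 in the authors' deposited table. Apoptosis regulators had a median of -0.07 but a test pointing up, without a call (adjusted p = 0.706). The word AAGTGCT lies in the 3′ UTRs of PTPRR, MRO, GINS4, CDC6 and CDKN1A.

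Across 19389 genes the knockdown effects in the 2 conditions, which share no library, had Pearson's r of 0.741 and Spearman's rho of 0.711. Genes are not independent replicates, so no p is given. The rises shared 2628 genes, against 787 for independent lists, and the falls shared 2701, against 849; 97 genes were called in opposite directions.

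The third comparison asks what gemcitabine did in shCTRL cells. As lists, cytokine, DNA replication and interferon-response genes were called up, and stress-response, G2/M, histone and mitochondrial transcripts down. Of 20002 genes 5599 changed, 2908 up and 2691 down, and 1738 changed by at least 1 (log2), 1342 up and 396 down. The largest rises in the authors' deposited table were TRAF1, a TNF receptor adaptor, at 6.30 ± 0.25, INHBA, another activin subunit, at 5.26 ± 0.33, the chemokine gene CXCL8 at 4.94 ± 0.38, CFAP58 at 4.70 ± 0.17, PTPRR at 4.47 ± 0.22 and CXCL1 at 4.30 ± 0.38. The largest falls in the authors' deposited table were DDIT4, an mTORC1 inhibitor, at -3.06 ± 0.17, HIST1H2AC at -2.99 ± 0.24, the helicase gene PIF1 at -2.58 ± 0.26, GLDN at -2.51 ± 0.29, the mitochondrial tRNA gene MT-TA at -2.42 ± 0.22 and the collagen gene COL8A1 at -2.22 ± 0.17.

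NF-kB and cytokine genes rose in 20 of 25 cases with gemcitabine and fell in 1 (21 and 1 adjusted over the list alone; median 1.75, adjusted p = 7.10e-31). IL6 was at 4.12 ± 0.22 and the NF-kB inhibitor gene TNFAIP3 at 4.08 ± 0.19 in the authors' deposited table. DNA replication genes rose in 32 of 38 cases and none fell (34 rose adjusted over the list alone; median 0.95, adjusted p = 1.72e-23). CDC6 was at 1.89 ± 0.14 and the transcription factor gene E2F1 at 1.31 ± 0.14 in the authors' deposited table. Homologous recombination and Fanconi genes rose in 13 of 29 cases and fell in 2 (15 and 2 adjusted over the list alone; median 0.38, adjusted p = 5.25e-05). BRCA2 was at 1.19 ± 0.17 and the exonuclease gene EXO1 at 1.21 ± 0.17 in the authors' deposited table. Interferon-response genes rose in 16 of 32 cases and none fell (17 rose adjusted over the list alone; median 0.67, adjusted p = 2.08e-08). CXCL10 was at 3.10 ± 0.33 and IRF1 at 1.65 ± 0.19 in the authors' deposited table. Of 28 p53 targets 7 rose and 2 fell (7 and 3 adjusted over the list alone; median 0.13, adjusted p = 0.0257, and 0.119 with ranks). CDKN1A rose by 1.36 ± 0.17 and the nuclease gene AEN by 1.71 ± 0.18 in the authors' deposited table.

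Integrated stress response genes fell in 14 of 20 cases with gemcitabine and rose in 2 (15 and 2 adjusted over the list alone; median -0.90, adjusted p = 1.80e-08). ATF4 fell by 1.28 ± 0.15 and ATF3 rose by 2.04 ± 0.26 in the authors' deposited table. G2/M genes fell in 12 of 32 cases and rose in 1 (13 and 1 adjusted over the list alone; median -0.25, adjusted p = 0.000944). The mitotic kinase gene PLK1 was at -1.47 ± 0.16 and the cyclin gene CCNB1 at -1.09 ± 0.19 in the authors' deposited table. Histone genes fell in 17 of 36 cases and rose in 1 (19 and 1 adjusted over the list alone; median -0.86, adjusted p = 1.14e-07), and mitochondrially encoded mRNAs fell in 11 of 13 (12 adjusted over the list alone; median -0.66, adjusted p = 5.41e-07). MT-ND4 was at -0.96 ± 0.14 in the authors' deposited table. Beside the histones, 83 other RNAs without a poly(A) tail had a median of -0.43, and 12 of these fell. Glycolysis genes fell in 8 of 20 cases and rose in 3 (9 and 3 adjusted over the list alone; median -0.31, adjusted p = 0.0257, and 0.135 among genes with a mean of 50 or more). The hexokinase gene HK1 was at -1.12 ± 0.16 in the authors' deposited table. Respiratory chain genes fell in 4 of 41 cases (2 adjusted over the list alone; median -0.19, adjusted p = 0.0375, and 0.161 among genes with a mean of 50 or more).

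Lists without a call for gemcitabine in shCTRL cells included gemcitabine metabolism, in which 5 of 18 rose and 4 fell (6 and 5 adjusted over the list alone; adjusted p = 0.98, median -0.06 but a test pointing up). RRM2, a subunit of ribonucleotide reductase, rose by 1.29 ± 0.20 in the authors' deposited table. The PIKK and TTT-R2TP list had no changed member of 13, also adjusted over the list alone (adjusted p = 0.98, median -0.01 but a test pointing up). In the checkpoint list 4 of 22 rose and 3 fell, as adjusted over the list alone (adjusted p = 0.641). CDC25A was at 1.51 ± 0.17 and the ATR mediator gene CLSPN at 1.40 ± 0.23 in the authors' deposited table. Apoptosis regulators had 6 of 22 higher and 3 lower (7 and 3 adjusted over the list alone; adjusted p = 0.587). Mesenchymal markers had 3 of 18 higher and 3 lower (3 and 4 adjusted over the list alone; adjusted p = 0.703, median -0.09 but a test pointing up). SOX9 was at 3.43 ± 0.37 and the repressor gene SNAI2 at 1.29 ± 0.14 in the authors' deposited table. Endothelial markers had a median of 0.11 but a test pointing down (adjusted p = 0.905). Of the genes named for gemcitabine in shCTRL cells, GLDN, COL8A1, PTPRR, CDC6, BRCA2, CDKN1A, AEN and RRM2 have AAGTGCT in their 3′ UTR.

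**Figure D1:**
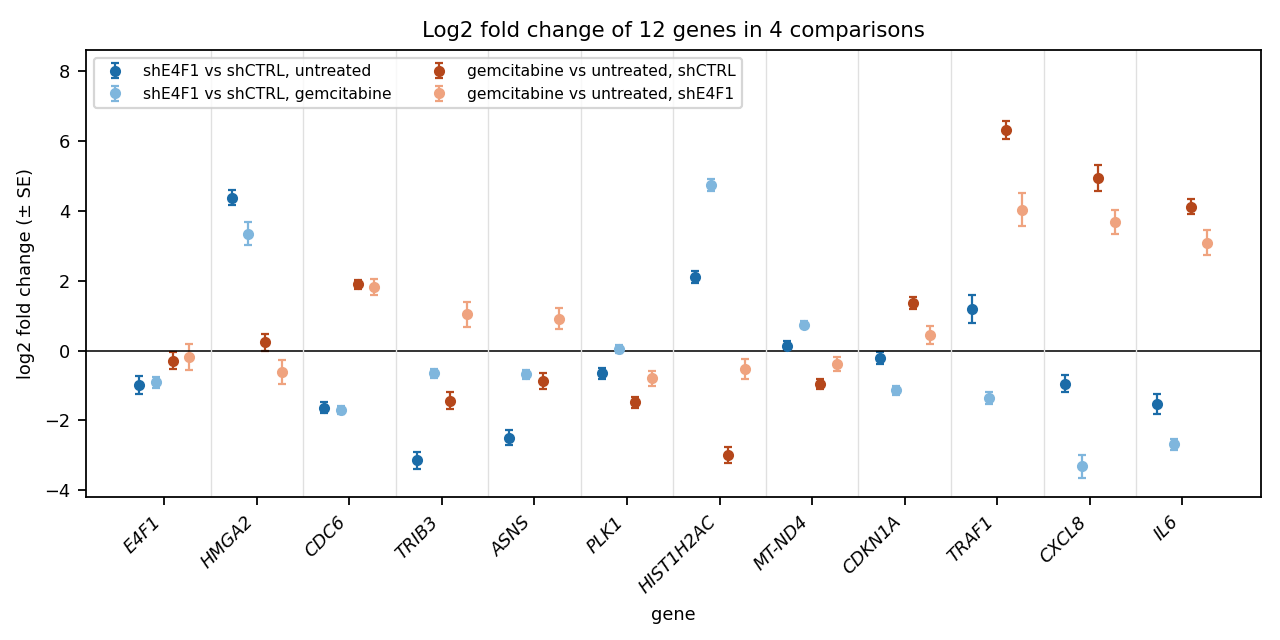
Log2 fold changes (vertical axis, log2 units) of 12 genes (horizontal axis) in 4 comparisons, each point with a bar of 1 SE either way; the first 3 comparisons are the authors' deposited tables and the last is derived from 2 of them. E4F1 was lower in both knockdown comparisons (-0.99 and -0.91), and TRAF1, CXCL8 and IL6 rose with gemcitabine by 6.30, 4.94 and 4.12 in shCTRL cells and by 4.04, 3.67 and 3.09 in shE4F1 cells.

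The fourth comparison, gemcitabine in shE4F1 cells, was derived as a difference of the authors' deposited tables. The replication, recombination, cytokine and interferon-response lists were called up. Of 21080 genes 234 passed, 195 up and 39 down, and 1350 had an unadjusted p under 0.05. The SE of this difference is too large (median 0.334, against 0.239 in shCTRL cells), and with the mean of both variances in place of their sum 1049 genes passed. The largest rises were TRAF1 at 4.04 ± 0.47, CXCL8 at 3.67 ± 0.35, INHBE at 3.54 ± 0.53, TNFRSF9, a TNF receptor family member, at 3.23 ± 0.49, IL6 at 3.09 ± 0.35 and the tight junction gene CLDN1 at 2.79 ± 0.66. The largest falls were MT-TA at -1.81 ± 0.29, PIF1 at -1.74 ± 0.31, the mitochondrial tRNA gene MT-TP at -1.60 ± 0.45, the cyclin gene CCNB3 at -1.39 ± 0.33, KIF20A at -1.33 ± 0.35 and the mitochondrial pseudogene MTND6P3 at -1.2 ± 0.35, which can share reads with MT-ND6 and lost its call on centring (adjusted p = 0.0560). TNFRSF9 and CLDN1 have AAGTGCT in their 3′ UTR.

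In shE4F1 cells 24 of 38 DNA replication genes rose with gemcitabine (33 adjusted over the list alone; median 1.07, adjusted p = 1.38e-88). E2F2 was at 2.12 ± 0.28 and E2F1 at 1.90 ± 0.23. The list p-values of this derived comparison cannot be set against those in shCTRL cells, since the spread of scores differs. They do not show a stronger response. Homologous recombination and Fanconi genes rose in 13 of 29 cases (20 adjusted over the list alone; median 0.77, adjusted p = 1.45e-45). EXO1 was at 1.94 ± 0.25 and BRCA1 at 1.34 ± 0.23. Cytokine genes rose in 12 of 23 cases (16 adjusted over the list alone; median 1.2, adjusted p = 6.09e-41). IL1A was at 2.66 ± 0.41. Interferon-response genes rose in 5 of 32 cases (6 adjusted over the list alone; adjusted p = 2.50e-07). CXCL10 was at 2.79 ± 0.50. The checkpoint list (2 of 22 higher, 4 adjusted over the list alone; adjusted p = 0.000204), p53 targets (2 of 29 higher, 3 adjusted over the list alone; adjusted p = 0.000372) and the integrated stress response (1 of 20 higher, 6 adjusted over the list alone; adjusted p = 0.000176, and 0.0764 with ranks) were called up. CDC25A was at 1.51 ± 0.21, DDB2 at 1.37 ± 0.29 and the stress transcription factor gene DDIT3 at 1.44 ± 0.32. Mitochondrially encoded mRNAs, glycolysis and histones had no single changed member over all genes, and 2, 0 and 0 fell adjusted over the list alone, but as lists they were called down (adjusted p = 8.78e-05, 9.24e-05 and 0.0016). The respiratory chain (median -0.14, adjusted p = 0.0202) and cholesterol synthesis (median -0.22, adjusted p = 0.0295), with 0 changed members each, also adjusted over the list alone, were called down, but not among genes with a mean of 50 or more (adjusted p = 0.0640 and 0.0806). G2/M genes fell in 3 of 32 cases, also adjusted over the list alone (adjusted p = 0.036, and 0.215 with ranks). CCNB1 was at -1.0 ± 0.27. The BH3-only gene PMAIP1 rose by 1.78 ± 0.32. E4F1 targets had 1 of 8 higher, also adjusted over the list alone, with a median of -0.15 but a test pointing up (adjusted p = 0.94).

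Across 19613 genes the gemcitabine effects in shCTRL and shE4F1 cells had Pearson's r of 0.577 and Spearman's rho of 0.520 (0.679 for Pearson's r among genes with a mean of 50 or more). The rises shared 181 genes, against 27.0 for independent lists, and the falls 34, against 5.35, with 0 genes called in opposite directions. Of the 5403 genes changed in shCTRL cells, 87.7% had the same sign in shE4F1 cells. The slope of the effect in shE4F1 cells on that in shCTRL cells, corrected for noise, was 0.464.

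**Figure D2:**
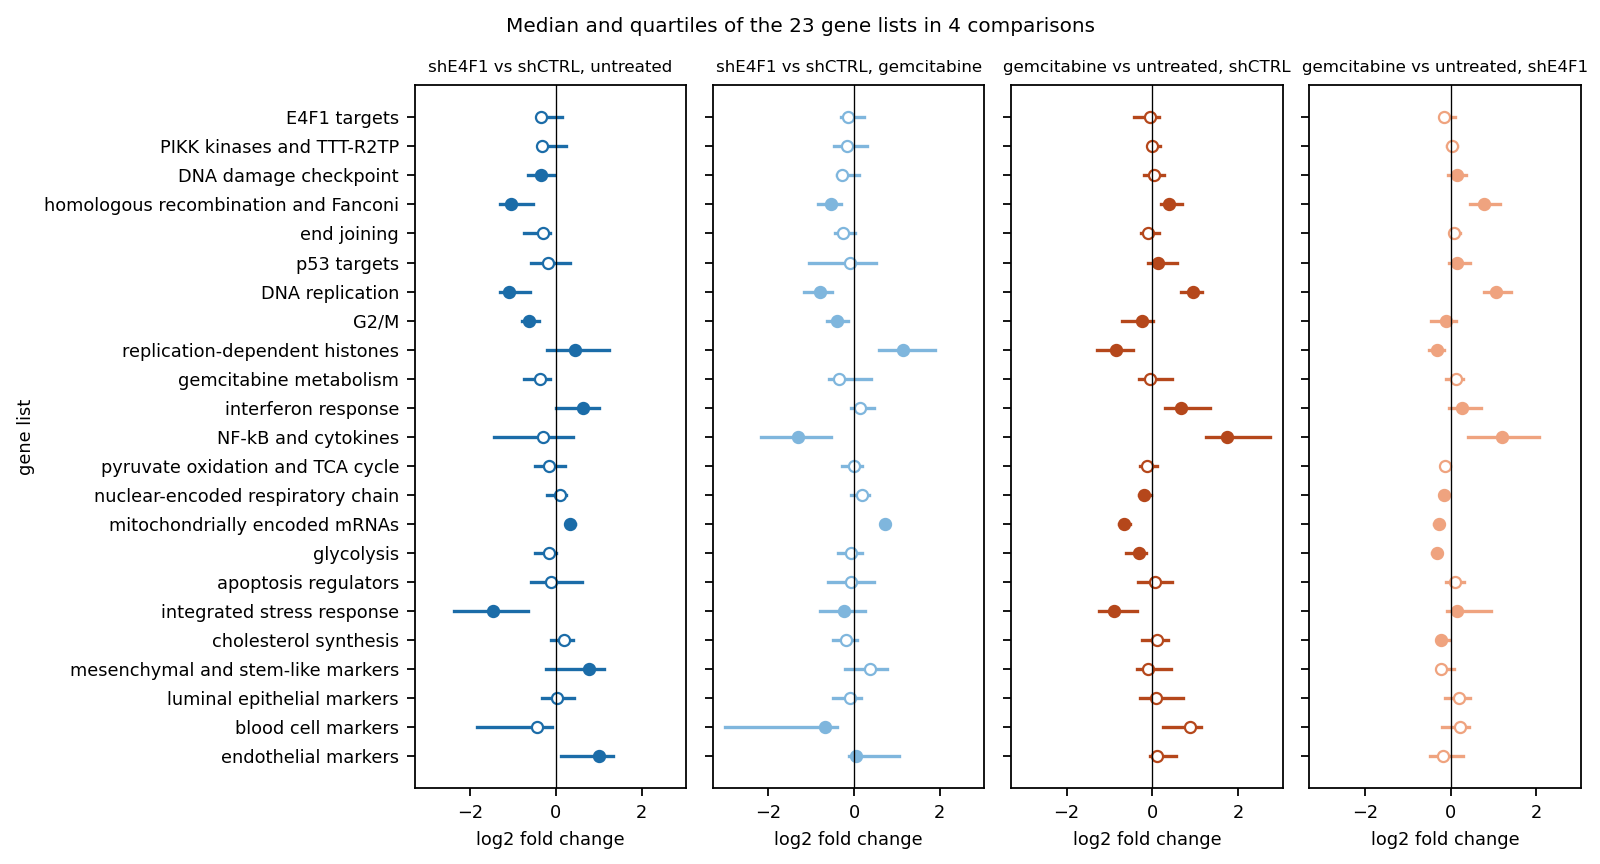
Median log2 fold change (horizontal axis, log2 units) of the measured members of each of the 23 fixed gene lists (vertical axis) in 4 comparisons; bars run from the lower to the upper quartile of the members, and filled points mark lists with an adjusted p under 0.05. DNA replication had a median of -1.09 and -0.79 in the knockdown comparisons, and of 0.95 and 1.07 with gemcitabine.

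The interaction asks whether the knockdown effect differed with gemcitabine. The integrated stress response list had a positive difference and the cytokine list a negative one. Of 20923 genes 1137 passed, 587 up and 550 down. Centring on the median of genes with a mean of 50 or more gave 1111, with 406 up and 705 down, because that median lay at 0.07 (log2). At an adjusted p under 0.01, 601 passed, and 462 changed by at least 1 (log2), 137 up and 325 down. The largest positive differences were INHBE at 2.92 ± 0.50, the glutathione-degrading enzyme gene CHAC1 at 2.88 ± 0.45, HIST1H2AC at 2.64 ± 0.26, DDIT4 at 2.54 ± 0.19, TRIB3 at 2.50 ± 0.28 and GLDN at 1.98 ± 0.43. The largest negative differences were INHBA at -3.97 ± 0.50, the cadherin gene FAT3 at -3.50 ± 0.46, the collagen gene COL3A1 at -3.48 ± 0.36, TRIML2 at -3.40 ± 0.56, PIWIL2 at -3.12 ± 0.58 and ACTBL2 at -3.05 ± 0.56; the 3′ UTRs of FAT3 and GLDN contain AAGTGCT.

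In the integrated stress response list 15 of 20 genes had a positive interaction (16 adjusted over the list alone; median 1.04, adjusted p = 4.66e-30). ASNS was at 1.82 ± 0.25 and the serine synthesis gene PSAT1 at 1.78 ± 0.24. Cytokine genes had a negative interaction in 9 of 23 cases and a positive one in 1 (13 and 1 adjusted over the list alone; median -0.75, adjusted p = 2.11e-10). TNFAIP3 was at -2.70 ± 0.23 and CXCL8 at -2.37 ± 0.42. Homologous recombination and Fanconi genes were positive in 7 of 29 cases (14 adjusted over the list alone; adjusted p = 1.00e-06). FANCE was at 1.02 ± 0.21. Histones were positive in 6 of 35 cases and negative in 1 (11 and 1 adjusted over the list alone; adjusted p = 1.00e-06), and mitochondrially encoded mRNAs were positive in 3 of 13 (7 adjusted over the list alone; adjusted p = 0.000155, and 0.0810 with the log2 change as the statistic). Interferon-response genes were negative in 3 of 32 cases and positive in 1 (6 and 1 adjusted over the list alone; adjusted p = 0.000374). The RNA sensor gene DDX58 was at -1.04 ± 0.22. G2/M (2 of 32 positive, 3 adjusted over the list alone; adjusted p = 0.00979) and cholesterol synthesis (1 of 18 negative, also adjusted over the list alone; adjusted p = 0.00717) lost their calls with the log2 change as the statistic (adjusted p = 0.117 and 0.0956). DNA replication was not called (7 of 38 positive and 1 negative, 8 and 1 adjusted over the list alone; adjusted p = 0.0708). Of p53 targets 3 of 29 were negative and 1 positive (4 and 2 adjusted over the list alone), with a median of 0.01 but a test pointing down (adjusted p = 0.731), and CDKN1A was at -0.92 ± 0.22. Median and test also differed in sign, without a call, for glycolysis (0.05, down, adjusted p = 0.881) and luminal markers (-0.03, up, adjusted p = 0.731).

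The last table sets shE4F1 cells under gemcitabine against untreated shCTRL cells, and so holds both changes at once. As lists, interferon-response and cytokine genes were called up and stress-response, G2/M and glycolysis genes down, and no call was made for DNA replication. Of 19724 genes 6345 changed, 3126 up and 3219 down, and 2371 changed by at least 1 (log2), 1422 up and 949 down. Among the largest rises in the authors' deposited table were TRAF1 at 5.22 ± 0.26, the cytokine gene IL34 at 4.74 ± 0.37, INHBA at 4.07 ± 0.39, HMGA2 at 3.78 ± 0.26 and SLC2A14 at 3.69 ± 0.34. The largest falls in the authors' deposited table were MEST at -3.39 ± 0.20, CRIM1 at -3.38 ± 0.18, the interleukin 33 receptor gene IL1RL1 at -3.02 ± 0.23, S100P at -2.97 ± 0.36, the Polycomb gene PHC2 at -2.79 ± 0.17 and RAB39B at -2.73 ± 0.44; MEST and IL1RL1 have AAGTGCT in their 3′ UTR.

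In that table interferon-response genes rose in 20 of 32 cases and fell in 1 (22 and 3 adjusted over the list alone; median 0.82, adjusted p = 1.72e-12). CXCL10 was at 3.61 ± 0.29 in the authors' deposited table. Cytokine genes rose in 16 of 24 cases and fell in 2, as adjusted over the list alone (median 0.94, adjusted p = 2.41e-08). Integrated stress response genes fell in 13 of 20 cases, also adjusted over the list alone (median -0.99, adjusted p = 1.56e-11), and G2/M genes in 22 of 32, also adjusted over the list alone (median -0.69, adjusted p = 2.31e-10). CCNB1 was at -1.66 ± 0.20 in the authors' deposited table. Glycolysis genes fell in 12 of 20 cases and rose in 2 (13 and 2 adjusted over the list alone; adjusted p = 0.0066, and 0.0576 among genes with a mean of 50 or more). The pyruvate kinase gene PKM was at -0.88 ± 0.18 in the authors' deposited table. Pyruvate oxidation and TCA cycle genes fell in 12 of 30 cases and rose in 3, as adjusted over the list alone (adjusted p = 0.0263, and 0.166 among genes with a mean of 50 or more). The pyruvate dehydrogenase subunit gene PDHA1 was at -1.11 ± 0.14 in the authors' deposited table, and its 3′ UTR contains AAGTGCT. DNA replication genes rose in 4 of 38 cases and fell in 5, as adjusted over the list alone (median 0.09, adjusted p = 0.704), and E4F1 was at -1.18 ± 0.27 in the authors' deposited table.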

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

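Of the tests given here, the slope among abundant genes was chosen only after its result was seen; the interaction was planned, and the other tests had their bounds set before they were run, on patterns already noticed in these data. Each result listed here drew attention because the knockdown effect under gemcitabine differed from that in untreated cells by a test of the difference itself. Such differences were found for 1137 genes.

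Integrated stress response genes had positive differences, at 2.50 for TRIB3, 1.82 for ASNS, 1.78 for PSAT1 and 1.45 for HERPUD1 (log2, list adjusted p = 4.66e-30). The median of this list was -1.47, -0.90 and -0.99 in the comparisons set against untreated shCTRL cells. It was -0.24 for the knockdown under gemcitabine and 0.16 for gemcitabine in shE4F1 cells. A shift of the untreated shCTRL libraries as a set therefore cannot be told apart from these changes. Histone genes also had positive differences, at 2.64 for HIST1H2AC, 1.89 for HIST1H2BD, 1.75 for HIST3H2A and 1.30 for HIST2H2BE (list adjusted p = 1.00e-06). Mitochondrial mRNAs stood at 0.60 for MT-ND4, 0.58 for MT-ND3 and 0.66 for MT-ATP8 (list adjusted p = 0.000155, with 0.0810 by the log2 change). Homologous recombination and Fanconi genes were at 1.15 for RMI2, 1.02 for FANCE, 0.86 for RAD54L and 0.75 for XRCC3 (list adjusted p = 1.00e-06). Of DNA replication genes, whose list was not called (adjusted p = 0.0708), CDT1 was at 1.04, CDC45 at 0.94, RFC4 at 0.79 and RFC2 at 0.61, and 1 member was negative. Mitotic genes were at 0.71 for PLK1 and 0.60 for CDC25B (G2/M adjusted p = 0.00979, with 0.117 by the log2 change and 0.0983 among genes with a mean of 50 or more). Cytokine genes were at -2.70 for TNFAIP3, -2.37 for CXCL8 and -0.84 for ICAM1 (list adjusted p = 2.11e-10). Interferon-response genes were at -1.04 for DDX58, -0.84 for IFI44 and -0.83 for IFIH1, and at 1.23 for XAF1 (list adjusted p = 0.000374). Targets of p53 went both ways, with SESN2 at 1.81, BTG2 at -1.15, PLK2 at -1.12 and CDKN1A at -0.92, and their list was not called (adjusted p = 0.731). IDI1 was at -0.82 (cholesterol synthesis adjusted p = 0.00717, with 0.0956 by the log2 change). Other negative differences were INHBA -3.97, FAT3 -3.50, COL3A1 -3.48, TRIML2 -3.40, PIWIL2 -3.12, ACTBL2 -3.05, SOX9 -2.24 and SNAI2 -1.17. Other positive differences were INHBE 2.92, CHAC1 2.88, DDIT4 2.54, GLDN 1.98, LAPTM5 1.49, PMAIP1 1.26, XBP1 1.23, NT5C 0.80, COX5A 0.75, ELP3 0.73, TK2 0.70, PDK1 0.58 and BCL2L1 0.56. Centring ended the calls of RFC2 (adjusted p = 0.0512), CDC25B (0.0646), MT-ATP8 (0.0699), NT5C (0.0711), MT-ND3 (0.0729), PDK1 (0.0819) and BCL2L1 (0.0916).

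A first pattern is a gemcitabine response that was smaller over all genes in shE4F1 cells (noise-corrected slope 0.464), though not for every list. Medians were not smaller for DNA replication (1.07, against 0.95 in shCTRL cells) or homologous recombination and Fanconi genes (0.77 against 0.38). The same held for the DNA damage checkpoint (0.15 against 0.05), p53 targets (0.15 against 0.13) and glycolysis (-0.32 against -0.31), among others. Cholesterol synthesis had the opposite sign (-0.22 against 0.11). So did the integrated stress response (0.16 against -0.90). Its list test gave adjusted p = 0.000176 in shE4F1 cells, or 0.0764 with ranks, and 1.80e-08 in shCTRL cells. Moderation of low-count fold changes is argued against as the whole cause of the smaller response in these libraries. Among 6851 genes with a mean of 1000 or more the noise-corrected slope was 0.532, below the bound of 0.8. Its SD was 0.0125 over 1000 bootstrap draws of genes. All genes come from the same libraries, so this SD does not measure the spread between libraries. A shift of the shCTRL gemcitabine libraries as a set cannot be told apart from the drug effect, because no other libraries stand for that group. Of the genes changed in shCTRL cells 87.7% had the same direction in shE4F1 cells, between the bounds of 60% and 90%. Of the 2524 with a mean of 1000 or more 90.3% did, just above the upper bound. A shift of the untreated shCTRL libraries cannot be told apart either. These libraries enter the response in shCTRL cells and cancel in the derived response of shE4F1 cells. Less gemcitabine uptake or activation may contribute: the nucleoside transporter gene SLC29A1 was lower in untreated shE4F1 cells, at -0.45 (SE 0.17, adjusted p = 0.0234) against a bound of -0.5, and the activating kinase gene DCK was at -0.20 (SE 0.18, adjusted p = 0.419), in the authors' deposited table. The bound was set for SLC29A1 and DCK only. The changes of ABCC5 and SAMHD1, which rose, and of DCTD, which fell, were not weighed. A response that depends on E4F1 stays open and untested.

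A second pattern is the fall of histone and mitochondrial transcripts with gemcitabine in shCTRL cells, which enters the interaction through the same libraries. A trend with transcript length as the whole cause is argued against, since the median of 48 histone genes and mitochondrial mRNAs was -0.67 (quartiles -1.08 and -0.42) after subtracting the median of the 500 genes nearest in length, and -0.77 before. For the histones, a change in the capture of RNA without a poly(A) tail may contribute and cannot be told apart: 83 other such RNAs had a median of -0.43 (quartiles -0.72 and -0.09), between the bounds of -0.5 and -0.2, and their median normalized count was only 7.32. A response of these transcripts to the drug stays open and untested.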

How the results depend on the processing

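Of the alternatives given here, only the added minimum fold change was planned; the others were chosen after seeing the data. With a minimum absolute change of 1 (log2), the counts were 2637 for the knockdown in untreated cells, 3048 under gemcitabine, 1738 for gemcitabine in shCTRL cells, 2371 for both changes and 462 for the interaction, against 7149, 9202, 5599, 6345 and 1137; fewer genes can pass by construction. At an adjusted p under 0.01 the interaction gave 601 genes and gemcitabine in shE4F1 cells 145, against 234; with the mean of the variances the latter gave 1049, as its SE is then smaller. Other counts stayed within 1.5 times. Centring gave 406 up and 705 down for the interaction (587 and 550 without it), 3739 and 3379 for the knockdown in untreated cells (3398 and 3751), 3355 and 2180 for gemcitabine in shCTRL cells (2908 and 2691), and 3540 and 2812 for both changes (3126 and 3219). The E4F1 change under gemcitabine from the other 2 tables was -0.89 (SE 0.37, adjusted p = 0.0772), weaker through the larger SE of a difference. For the knockdown effects Pearson's r was 0.804 and 0.842 among genes with a mean of at least 50 and 1000; for the gemcitabine effects it was 0.679 and 0.689, and Spearman's rho was 0.520; the cause was not tested. Of 138 list tests 57 were called, against 51 with ranks, 47 with the log2 change and 49 among genes with a mean of 50 or more; calls were lost in 8, 14 and 10 cases and gained in 2, 4 and 2, with no direction turned where a call was made. Of single named genes, 34 lost their call and 283 kept their side of the threshold with the other tables; centring ended 13 calls, added 5 and left 613. No paired analysis was possible because the libraries of the count table carry no label, so a fit with the replicate number could not be made. For the same reason the other alternatives that had been planned (another count test, other normalizations, low-count filters, robust dispersion, only the compared groups, each library left out, an estimated list correlation) and other splits of the samples were not run. Low counts limit the derived comparisons: the median SE of the interaction was 0.734 for genes with a mean under 10 and 0.185 from 1000.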

Other observations

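All families and 3′ UTR words in this part were chosen after the data were seen, and 20 families were tested per comparison. The knockdown effect went with transcript length among genes with a mean of 50 or more. Spearman's rho was 0.253 in untreated cells and 0.166 under gemcitabine. In untreated cells the median was -0.11 below 1000 bases and 0.10 from 4000. No list or family test was adjusted for length, so its share in these calls is unknown. In untreated shE4F1 cells 14 of 20 cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs, fell and none rose (median -0.68, adjusted p = 4.24e-06), with MARS at -1.64 ± 0.19 and GARS at -1.41 ± 0.18 in the authors' deposited table. Their interaction with gemcitabine was positive in 9 of 20 cases (adjusted p = 6.91e-08). Host genes of small nucleolar RNAs fell in 13 of 22 cases and rose in 2 (median -0.71, adjusted p = 0.000400), with SNHG1 at -2.25 ± 0.24 and SNHG14 at 1.42 ± 0.13 in the authors' deposited table. Mitochondrial ribosomal protein genes fell in 29 of 77 cases and rose in 4 (median -0.26, adjusted p = 0.000883), with MRPS10 at -1.73 ± 0.15 in the authors' deposited table. Proteasome subunit genes fell in 13 of 37 cases and rose in 2 (median -0.26, adjusted p = 0.00600), with PSMC2 at -1.29 ± 0.15 in the authors' deposited table. Matrix metalloproteinase genes rose in 7 of 13 cases (median 0.68, adjusted p = 0.000857), with MMP15 at 1.68 ± 0.29 and MMP2 at 0.96 ± 0.17 in the authors' deposited table.

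With gemcitabine in shCTRL cells 52 of 85 cytosolic ribosomal protein genes fell and none rose (median -0.41, adjusted p = 3.08e-12), with RPL3 at -0.62 ± 0.14 in the authors' deposited table. Under gemcitabine 43 of the 85 were higher and 5 lower with shE4F1 (median 0.29, adjusted p = 0.00552), against the same shCTRL libraries. Zinc finger (ZNF) genes rose in 169 of 481 cases and fell in 24 (median 0.30, adjusted p = 4.68e-06), with ZNF93 at 1.81 ± 0.26 in the authors' deposited table, and their interaction was negative in 24 cases and positive in 9 (adjusted p = 2.72e-05). Mitochondrial tRNAs fell in 11 of 20 cases (median -0.92, adjusted p = 3.64e-07), and rose with shE4F1 in 8 untreated (adjusted p = 0.00732) and 14 under gemcitabine (adjusted p = 0.0110).

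A further pattern is the set of 666 genes that were lower with shE4F1 by at least 1 (log2) in both conditions. Of them 83.8% had a mean normalized count of 50 or more. Genes that pass the threshold are mostly abundant: 6279 of 7142 genes changed in untreated cells reached that mean. The share therefore cannot tell whether low counts contributed to the 666 genes. Off-target seed matches of the hairpin may contribute: AAGTGCT was the most enriched word in their 3′ UTRs, with an odds ratio of 3.69 (95% interval 2.98 to 4.57, one-sided Mantel-Haenszel chi-square test, Bonferroni p = 7.94e-29), against 0.42 in genes higher in both conditions and 1.08 in genes lower with gemcitabine. Alu repeats, which hold this word, are argued against, since the odds ratio was 3.84 (95% interval 3.02 to 4.89) once UTRs with the Alu core GGGATTACAGG or its reverse complement were left out. An effect of lower E4F1 itself stays open and untested. Of 29 DNA replication genes without the word 26 fell in untreated cells and 28 under gemcitabine. Their medians were -1.09 and -0.63, against -1.09 and -1.18 for the 9 with the word. This split cannot separate an effect of E4F1 from an off-target one, since genes without the word could fall indirectly under either.

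AAGTGCT lies at 2 coding sites of E4F1, of which 1 is at 2232770 to 2232776 in exon 6. The other lies in the longer word CAAGTGCTA, in exon 11 of 14 (9 of 12 in another transcript), at 2234714 to 2234722 on chromosome 16 (GRCh38), within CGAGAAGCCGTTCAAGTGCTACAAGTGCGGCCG. AAGTGCTA had an odds ratio of 4.78 and lay in 12.7% of the lower genes and 4.06% of the others. The exon 6 site reads AAGTGCTC, which had an odds ratio of 2.26 and lay in 5.31% and 2.94%. AAGTGCTG and AAGTGCTT, which lie in no E4F1 transcript, had odds ratios of 2.32 and 2.07. How often AAGTGCT lies in coding sequences of other genes was not counted. The hairpin sequence was not analysed here, so whether it matches that site was not tested. Over all searched genes AAGTGCT went with a small shift in medians that were not matched for UTR length. In untreated cells 2679 genes with AAGTGCT had a median of -0.11 and 8693 without it -0.04, and under gemcitabine -0.09 and 0.05. The log2 change itself went with transcript length. In untreated cells its median was 0.10 for transcripts from 4000 bases and -0.11 below 1000, among genes with a mean of 50 or more. The size of the shift at like length is therefore unknown. Of 818 genes higher by at least 1 (log2) in both conditions, the 451 with a mean of at least 50 and a searched 3′ UTR were most enriched for AAGAGCA, with an odds ratio of 1.83 (one-sided Mantel-Haenszel chi-square test, Bonferroni p = 0.000778).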
